A study of Marchantia polymorpha with 78 samples.

How the data were processed

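RNA of Marchantia polymorpha Tak-1, a male wild-type line of this liverwort, was measured by poly(A) RNA sequencing in 78 libraries of 26 groups with 3 biological replicates each. Per the labels, gemmae grew for 8 days in continuous white light at 23 °C and then stood for 24 h in darkness. Plates then stayed in darkness or went into far-red, red, blue or white light and were sampled after 30 min, 60 min, 180 min, 12 h and 24 h; a time-zero group was taken at the end of the dark period. Each library holds the pooled thalli of 3 plants. The monochromatic lights had emission maxima of 430, 660 and 730 nm. Per the labels, intensities were 50 to 60 µmol m⁻² s⁻¹ for white, 30 to 40 for blue, 80 to 90 for red and 30 to 40 for far-red light. The labels state that each culture plate held 3 biological replicates, so plate and treatment cannot be told apart.

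The authors' processing gave a table of TPM (the deposited unit, transcript abundance scaled to a fixed sum per library) for 19355 genes in the 78 libraries, from paired-end reads of 150 bases. Every deposited column was checked and sums to 1000000. STAR is the only tool named in the submitters' processing notes; its version, the genome build, the annotation, the quantification tool and any filter are not given in the sources used here. A further deposited table, with 26 columns, was checked and equals the mean of the 3 replicates' TPM within 1e-06; it was not analysed separately. Read counts cannot be recovered from TPM, so the depth of each library is unknown and no counting interval or detection floor is given. Between 14791 and 15585 genes per library were above 0 TPM and between 11838 and 12262 reached 1 TPM. Of all values 21.2% were 0, and 576 genes were at 0 in every library.

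Genes are named by matching the number in each identifier to locus tags of a name table for assembly MpTak2_v7.1. Of the identifiers 17384 matched one of 18136 protein-coding tags, and 3091 carried a symbol. The match was tested in 2 ways. The table skips 61 numbers of the autosomal series and the name table skips 59 of these, against 5.7 by chance. Mean correlation among members of a gene family was 0.717 for the replication licensing (MCM) genes at the match, against −0.252 to 0.139 with shifted numbers. It was 0.400 for core histones against −0.041 to 0.198, and 0.228 for pentatricopeptide repeat proteins against 0.009 to 0.052. No genome came with the data, so no coordinates are printed. Of the identifiers, 154 lie on the V chromosome and 143 on unplaced sequence.

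Genes with at least 1 TPM in 3 or more libraries were kept (13054 genes). TPM plus a pseudocount of 1 was log2 transformed with no further scaling. All 78 libraries were fitted together with limma 3.58.1 in R 4.3.3, with 1 mean per group and an intensity trend of the prior variance (trend=TRUE). For each light, the 5 differences from darkness at the same time were tested together by limma's moderated F test. The same was done for blue minus red, red minus far-red, and continued darkness minus time zero. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its largest log2 fold change was at least 1 in size. Each of 35 contrasts at single times was also tested on its own with the same thresholds. Time dependence was tested as the response at 24 h minus that at 30 min. Fold changes are on the log2(TPM + 1) scale, which understates changes of genes near 0. Errors of TPM are SD over 3 libraries and errors of log2 fold changes are SE from the fit. On simulated changes in these libraries, all 50 genes changed by 1.5, all 50 changed by 2 and all 50 changed by 3 (log2) were called between white light and darkness at 30 min. Of 50 genes changed by 0.7, 0 were called, since this lies below the fold threshold, though 50 had an adjusted p under 0.05. There were 0 false calls by limma, and 7 unchanged genes had an adjusted p under 0.05. Changes were simulated, with normal noise, only in genes above about 5 TPM in darkness at 30 min. Recovery of genes below that level was not tested.

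Named genes follow a rule: the 3 largest rises and the 3 largest falls among called genes with a symbol, for each light at 30 min, 180 min and 24 h. For blue against red the 5 largest in each direction were taken at the same times. For red against far-red the 3 largest in each direction were taken at 30 min and 24 h, and for darkness against time zero at 180 min and 24 h. Of each gene list described, up to 2 called members with the largest rise and up to 2 with the largest fall are named, and every measured member of the photoreceptor list. Groups, tests, thresholds, this rule, the themes of the lists and the alternatives were fixed before the data were examined, except where stated.

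The 35 gene lists were written as symbols after the name table was seen. The lists of plastid sigma factors with flavodiiron proteins and terminal oxidases, the plastid isoprenoid (MEP) pathway, dirigent proteins, polyphenol oxidases, terpene synthases, lipoxygenases, pentatricopeptide repeat proteins and cupins were themes added at that point, before any expression value was compared. Those of cuticle and surface wax, rhizoid and gemma regulators, gibberellin-related genes and male gamete markers were narrowed or widened then. Lists were tested with camera (preset correlation 0.01, adjusted over 1225 tests of 35 lists in 35 contrasts), with camera with an estimated correlation and with fry. The camera test asks whether the genes of a list moved more than other genes did. With the preset correlation 312 tests passed, and with an estimated correlation 2 did: gibberellin-related genes in blue against red light at 24 h, and reactive oxygen scavenging genes in red against far-red light at 24 h. The fry test, which asks whether the genes of a list move on balance in one direction, passed 903. Counts of called members were adjusted over all genes tested; the count adjusted over the list alone was the same in 1223 of the 1225 tests.

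Alternatives were: a pseudocount of 0.1 or 5, no filter or a filter at 10 TPM, trimmed-mean (TMM) factors or quantile normalization, a fit without trend and with robust priors, only the groups of the comparison, the replicate number as a block, each replicate number left out of every group in turn, time zero as the reference, the adjusted p alone, and a fold threshold of 2 (log2). Leaving out the 60 min libraries, leaving out single libraries and subtracting the median of each contrast were added after the data were seen. Other groupings of the libraries were drawn 100 times per result, or in all 10 ways for 3 against 3 libraries, with a fixed seed. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.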

Results

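The data were 78 poly(A) RNA libraries of Tak-1 thalli in 26 groups of 3 biological replicates: time zero, and darkness or white, blue, red or far-red light for 30 min, 60 min, 180 min, 12 h and 24 h. Values are TPM, and the depth of each library is unknown. Replicates of a group correlated across genes with r between 0.9942 (darkness at 60 min) and 0.9983, with a median of 0.9978; genes are not independent replicates. The first principal component of the 13054 tested genes held 56.7% of the variance and the next 11.8%. The 50 genes of highest TPM held between 13.6% and 20.83% of TPM per library, with 19.36% ± 0.21 (SD, n = 3) in darkness at 30 min and 17.02% in darkness at 24 h. The median log2 difference of all tested genes from darkness passed 0.1 at 30 and 60 min of white (0.134 and 0.145), blue (0.169 and 0.185) and red light (0.172 and 0.204), and in far-red light at 60 min (0.12) and 24 h (0.12). With TMM factors these medians were −0.057, −0.033, −0.07, −0.043, −0.064, −0.037, −0.04 and −0.014. Shares of rises are therefore also given with that scaling. Changes given beside a gene name without a unit are log2 fold changes. Rises and falls in light are differences from darkness at the same time. Darkness itself had 518 genes called against time zero over the time course. The 114 gene values picked as the largest called changes of a contrast had a limma adjusted p of at most 0.013. Replicate 3 of darkness at 60 min stood apart from the other 2 toward the dark libraries of 180 min. Its second principal component was 17.41 against 25.79 and 28.2 (11.94 to 14.26 at 180 min), and its 50 genes of highest TPM held 17.84% against 20.15% and 20.83%. Each comparison with darkness at 60 min uses it, so counts and called lists at 60 min are also given without it.

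**Figure D1:**
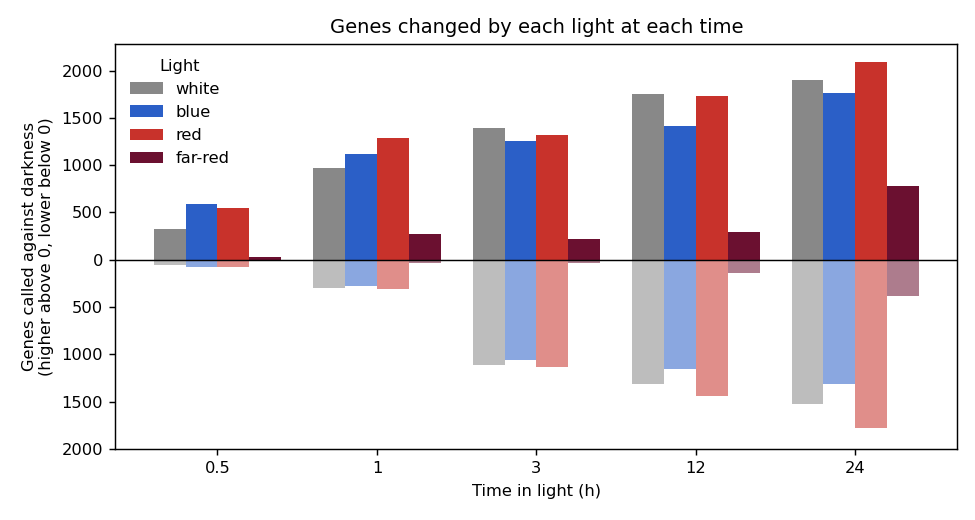
Genes called higher (above 0) and lower (below 0) than darkness at the same time in white, blue, red and far-red light, in numbers of genes, against time in h. Bars are counts of 13054 tested genes, 3 libraries per group. Red light reached 2088 higher and 1775 lower at 24 h, far-red light 780 and 389.

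White light was the light in which the plants had been grown, and against darkness it answers which genes respond to a return to light. After 30 min, MpBBX2 (Mp3g20050), a B-box zinc finger factor, was at 15.1 ± 0.979 TPM against 0.649 ± 0.359 in darkness (SD, n = 3; log2 3.31, SE 0.17), and the chalcone synthase family gene MpPKS/CHS14 (Mp4g14190) at 61.7 ± 10.8 against 7.08 ± 0.10. MpMAPKKK10 (Mp4g08320), a MAP kinase kinase kinase, rose by 3.15. MpPOD158 (Mp7g17080, −1.78), MpEXL6 (Mp7g05040, −1.42) and MpPOD169 (Mp8g16260, −1.37) had the largest falls. At 180 min the fatty acid elongase gene MpELO2 (Mp3g20100) was at 99.6 ± 4.08 TPM against 5.99 ± 0.284 (log2 3.85, SE 0.13), the helicase subunit gene MpMCM6 (Mp4g14930) at 26.8 ± 2.79 against 1.38 ± 0.150 (3.54, SE 0.15), and MpCYP704-like5 (Mp2g06910) had risen by 3.11. The factor gene MpERF10 (Mp7g00860) was at 4.03 ± 0.350 TPM against 198.5 ± 8.65 (log2 −5.31, SE 0.11), and MpEXL3 (Mp7g19240, −3.90) and the phosphatase gene MpPP2C_F3 (Mp4g14730, −3.77) were also lower.

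At 24 h of white light, the B-type cyclin gene MpCYCB_1 (Mp5g10030) was at 94.0 ± 5.62 TPM against 2.73 ± 0.607 in darkness (log2 4.68, SE 0.11), the methyltransferase gene MpOMT8 (Mp2g07390) at 55.7 ± 3.81 against 0.868 ± 0.496 (4.95), and MpCYP704-like5 at 79.7 ± 3.77 against 1.80 ± 0.324 (4.86). MpCYCB_1 had itself fallen from time zero in darkness by 24 h, so part of its difference is a fall of the reference. MpMLS5 (Mp8g16290) was at 0.587 ± 0.270 TPM against 90.1 ± 4.88 (log2 −5.85, SE 0.13), and MpDIR39 (Mp5g16510, −5.52) and MpLEA-like12 (Mp3g04820, −5.47) fell about as far. Of 40 measured histone and replication licensing genes, 24 rose at 24 h, 1 fell and 15 were not called (camera adjusted p = 4.4e-06; adjusted p = 0.093 with an estimated correlation). MpH3.1a rose by 4.14 and MpH3.1e by 4.12, and MpH2A.X.2 fell by 1.96. In darkness this list had itself moved down from time zero by 24 h, while MpH2A.X.2 had risen. Of 19 cell cycle regulators, 9 rose at 12 h and 0 fell (camera adjusted p = 0.023; adjusted p = 0.52 with an estimated correlation), and 8 rose at 24 h (camera adjusted p = 0.051, not called), with MpCDKB, a kinase of the division cycle, at 4.14; without replicate 1 or 2 of either group alone that list was called (0.039 to 0.048). Like MpCYCB_1, MpCDKB had fallen from time zero in darkness by 24 h. Of 64 late embryogenesis abundant (LEA) and dehydrin genes, which are linked to drying tolerance, 35 fell, 1 rose and 28 were not called (camera adjusted p = 1.7e-06; adjusted p = 0.51 with an estimated correlation). MpDHN1 fell by 5.36 and MpLEA-like13 rose by 1.22. The same list had 17 rises and 1 fall at 60 min, without a call of the list (camera adjusted p = 0.19). MpLEAL5 rose by 3.41, MpLEA-like18 by 3.22, and MpLEA-like33 fell by 1.15. Of 5 chlorophyll and haem synthesis genes, 3 rose at 24 h and 0 fell (camera adjusted p = 0.0077; adjusted p = 0.25 with an estimated correlation). MpGUN5, the large subunit of magnesium chelatase, was at 706.9 ± 43.5 TPM against 115.1 ± 7.24 (log2 2.61, SE 0.07), and MpCHLD rose by 2.07. Of 116 class III peroxidases, 45 rose, 10 fell and 61 were not called at 24 h (camera adjusted p = 0.016; adjusted p = 0.64 with an estimated correlation). MpPOD99 stood at 3.68, MpPOD126 at 3.19, MpPOD143 at −2.87 and MpPOD164 at −2.80.

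At 60 min of white light, 4 of 6 B-box factors rose and 0 fell (camera adjusted p = 0.0032; adjusted p = 0.3 with an estimated correlation), MpBBX2 by 5.37 and MpBBX3 by 3.41. Of 66 phenylpropanoid and flavonoid synthesis genes, 23 rose, 1 fell and 42 were not called (camera adjusted p = 0.0015; adjusted p = 0.35 with an estimated correlation). MpPKS/CHS21 and MpPKS/CHS14 each rose by 3.86, and MpHCT fell by 1.08. Of 7 circadian clock genes, 3 rose and 0 fell (camera adjusted p = 0.041; adjusted p = 0.55 with an estimated correlation), among them MpELF3 by 2.63 and MpPRR by 2.01. Without replicate 3 of darkness at 60 min these lists had camera adjusted p of 0.0042, 0.0034 and 0.029, with 4, 24 and 3 rises, and 1502 genes in place of 1271 were called. Over the time course 4878 of 13054 genes (37.4%) were called by limma, 2899 with a rise and 1979 with a fall as their largest change. By time, 325 genes were higher and 57 lower at 30 min, 967 and 304 at 60 min, 1390 and 1114 at 180 min, 1748 and 1310 at 12 h, and 1899 and 1524 at 24 h. With TMM factors rises were 63.1% of the calls at 30 min in place of 85.1%, 57.8% at 60 min in place of 76.1%, 48.3% at 180 min in place of 55.5%, 50.1% at 12 h in place of 57.2%, 51.3% at 24 h in place of 55.5%, and 52.9% over the time course in place of 59.4%.

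**Figure D2:**
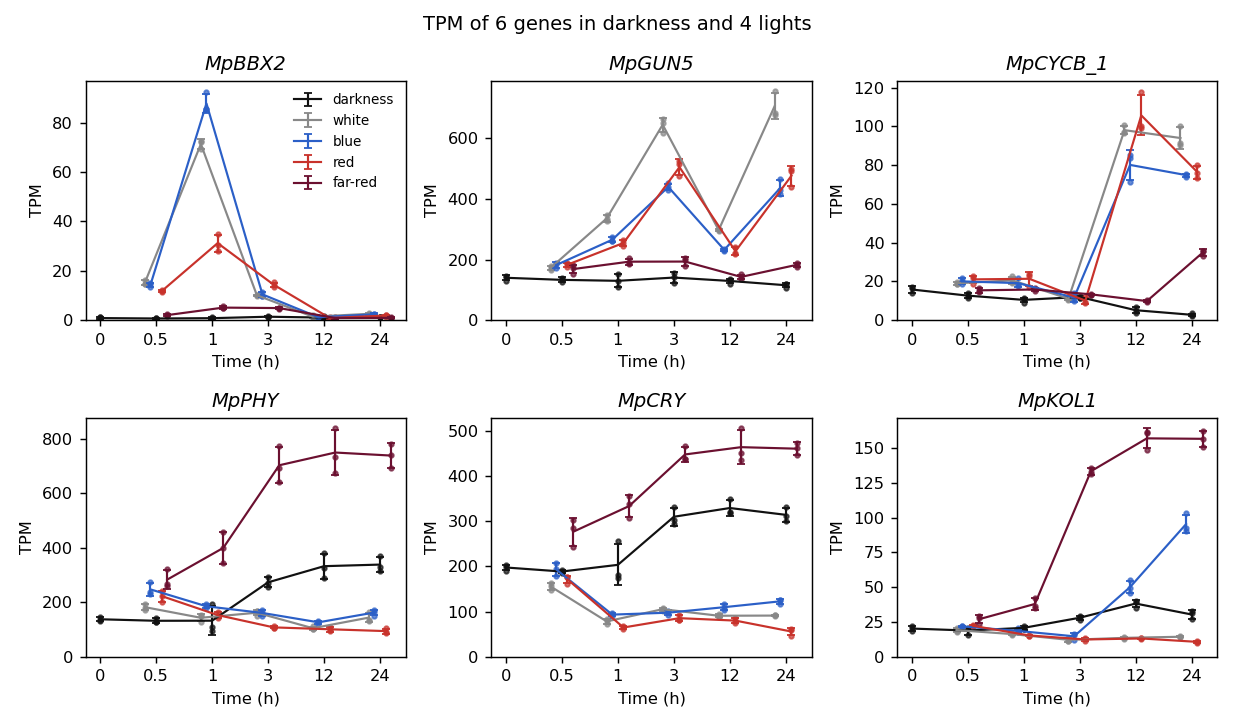
TPM of MpBBX2, MpGUN5, MpCYCB_1, MpPHY, MpCRY and MpKOL1 against time in h (times evenly spaced, not to scale), by light; points are libraries, lines join the means of 3 libraries and bars are SD. MpGUN5 reached 706.9 TPM at 24 h of white light and stood at 182.7 in far-red light and 115.1 in darkness.

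Among the largest rises of genes with a symbol in blue light were a MYB factor gene at 30 min, 2 flavonoid genes at 180 min, and a cyclin and a polyphenol oxidase gene at 24 h. After 30 min, MpR2R3-MYB5 (Mp8g11870), a MYB factor, was at 106.7 ± 1.89 TPM against 12.6 ± 1.11 in darkness (log2 2.99, SE 0.10, n = 3). MpMAPKKK10 rose by 3.35 and MpBBX2 by 3.24. MpERF23 (Mp5g01050, −1.74, SE 0.53, and not called without replicate 1), MpExpansin34 (Mp4g22180, −1.64) and MpPOD158 (−1.47) were lower. At 180 min the chalcone synthase family gene MpPKS/CHS2 (Mp2g07060) was at 872.5 ± 5.49 TPM against 45.6 ± 2.65 (log2 4.23, SE 0.06), MpF3H (Mp1g26540), flavanone 3-hydroxylase, at 1068 ± 7.48 against 70.8 ± 4.34 (3.90, SE 0.06), and MpELO2 at 161.2 ± 9.36 against 5.99 ± 0.284 (4.54). MpERF10 (−4.18), MpEXL3 (−3.99) and MpPTB8 (Mp4g19700, −3.60) were lower. At 24 h MpCYCB_1 was at 74.9 ± 0.737 TPM against 2.73 ± 0.607 (4.36), the polyphenol oxidase gene MpPPO71 (Mp5g20040) at 121.3 ± 8.19 against 5.32 ± 1.07 (4.28), and the peroxidase gene MpPOD99 (Mp5g13710) at 32.4 ± 1.61 against 0.748 ± 0.276 (4.27). Both MpCYCB_1 and MpPPO71 had fallen from time zero in darkness by 24 h. For MpPPO71 that fall made up most of the log2 difference. MpLEA-like12 (−6.10), the dehydrin gene MpDHN1 (Mp6g07540, −5.68) and MpLEA-like14 (Mp3g08260, −5.43) had the largest falls.

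At 30 min of blue light, 9 of 46 MYB factors rose and 0 fell (camera adjusted p = 4.4e-06; adjusted p = 0.43 with an estimated correlation), with MpGCAM1, a regulator of gemma cup formation, at 2.31. Of 36 bHLH factors, 5 rose and 0 fell (camera adjusted p = 1e-04; adjusted p = 0.43 with an estimated correlation), MpBHLH7 by 1.53 and MpBHLH41 by 1.40. Of 71 pentatricopeptide repeat proteins, which act on organelle RNA, 3 rose and 0 fell (camera adjusted p = 0.00015; adjusted p = 0.55 with an estimated correlation), MpPPR_43 by 1.14 and MpPPR_42 by 1.02. At 24 h, 4 of 9 genes of the plastid isoprenoid (MEP) pathway rose and 0 fell (camera adjusted p = 0.0042; adjusted p = 0.093 with an estimated correlation), MpDXS2 by 1.94 and MpHDR by 1.67. Of 57 cell wall enzymes, 21 rose, 3 fell and 33 were not called (camera adjusted p = 0.0035; adjusted p = 0.42 with an estimated correlation). MpCE8.10 stood at 3.63, MpPL1.3 at 3.37, MpGH16.40 at −1.77 and MpGH28.6 at −1.49. Of 36 polyphenol oxidases, 16 rose, 2 fell and 18 were not called (camera adjusted p = 0.017; adjusted p = 0.54 with an estimated correlation). MpPPO17 stood at 3.92, MpPPO32 at −2.82 and MpPPO19 at −1.29. MpPPO17 was also among the largest falls from time zero in darkness at 24 h. Of the 64 LEA and dehydrin genes, 39 fell and 1 rose (camera adjusted p = 1.9e-07; adjusted p = 0.43 with an estimated correlation). Limma called 4947 genes (37.9%) over the time course, 3054 with a rise and 1893 with a fall as their largest change. By time, 588 genes were higher and 80 lower at 30 min, 1118 and 275 at 60 min, 1258 and 1056 at 180 min, 1410 and 1154 at 12 h, and 1768 and 1317 at 24 h. With TMM factors 400 genes in place of 668 were called at 30 min, rises were 60.5% of these in place of 88%, and they were 54.7% at 60 min in place of 80.3%, 49.5% at 180 min in place of 54.4%, 51.2% at 12 h in place of 55%, 54.6% at 24 h in place of 57.3%, and 55.1% over the time course in place of 61.7%. Without replicate 3 of darkness 1670 genes in place of 1393 were called at 60 min.

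Red light gave the highest counts of the 4 lights over the time course, with 2 chalcone synthase family genes among the largest rises of genes with a symbol at 30 min. After 30 min, MpPKS/CHS21 (Mp7g14930) was at 15.5 ± 3.82 TPM against 0.671 ± 0.205 in darkness (log2 3.29, SE 0.17, n = 3). MpMAPKKK10 rose by 3.32 and MpPKS/CHS14 by 3.22. MpPOD158 (−1.86), MpExpansin34 (−1.72) and the F-box gene MpKFB01_20 (Mp6g10520, −1.58) were lower. At 180 min the glycoside hydrolase gene MpGH31.8 (Mp8g10240) was at 102.3 ± 10.6 TPM against 5.15 ± 0.851 (log2 4.07, SE 0.12), MpPKS/CHS14 at 139.9 ± 10.02 against 8.00 ± 2.16 (3.99), and the glycosyltransferase gene MpUGT31 (Mp7g01270) at 190.3 ± 6.58 against 11.3 ± 0.385 (3.96). MpERF10 (−5.19), MpPTB8 (−3.93) and MpEXL3 (−3.84) were lower. At 24 h MpCYP704-like5 was at 93.1 ± 5.80 TPM against 1.80 ± 0.324 (5.08), MpCYCB_1 had risen by 4.39 and MpCYP827A1 (Mp5g12720) was at 57.9 ± 5.20 against 1.93 ± 0.576 (4.34). Here too part of the difference of MpCYCB_1 is its fall from time zero in darkness. MpMLS5 (−6.12), MpDIR39 (−6.06) and MpPP2C_F3 (−5.14; 1.73 ± 0.181 TPM against 95.2 ± 3.82) had the largest falls.

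At 24 h of red light, 13 of 28 reactive oxygen scavenging genes rose, 2 fell and 13 were not called (camera adjusted p = 0.00043; adjusted p = 0.093 with an estimated correlation). The glutathione peroxidase gene MpGPX2 rose by 2.43 and the reductase gene MpMDHAR3 by 1.93, and MpSOD3 fell by 1.25 and MpDHAR4 fell by 1.01. Of 13 WRKY factors, 7 fell and 0 rose (camera adjusted p = 0.0013; adjusted p = 0.42 with an estimated correlation), MpWRKY8 at −4.01 and MpWRKY14 at −3.26. Of 16 gibberellin-related genes, 9 fell, 1 rose and 6 were not called (camera adjusted p = 0.0059; adjusted p = 0.3 with an estimated correlation). MpGID1L6 stood at −2.41, MpKAOL2 at −2.01 and MpKOL3 at 1.90. Of 31 auxin synthesis, transport and response genes, 13 fell, 4 rose and 14 were not called (camera adjusted p = 0.0061; adjusted p = 0.48 with an estimated correlation). MpSAUR10 stood at −2.76, MpSAUR13 at −2.61, MpSAUR4 at 2.41 and MpGH3A at 1.84. Of 26 cytokinin, ethylene and abscisic acid genes, 7 fell and 0 rose (camera adjusted p = 0.0028; adjusted p = 0.52 with an estimated correlation). MpCKX1, a cytokinin oxidase, fell by 3.58 and the response regulator gene MpRRA fell by 2.86. Of 21 autophagy genes, 3 fell and 0 rose (camera adjusted p = 0.015; adjusted p = 0.55 with an estimated correlation), among them MpATG8a at −1.19 and MpATG8b at −1.17. Of 13 lipoxygenases, 5 fell and 0 rose (camera adjusted p = 0.04; adjusted p = 0.55 with an estimated correlation), among them MpLOX1 at −2.54 and MpLOX10 at −2.25. Of the 64 LEA and dehydrin genes, 29 fell, 3 rose and 32 were not called (camera adjusted p = 0.00058; adjusted p = 0.61 with an estimated correlation). Among 36 expansins, 14 rose and 4 fell without a call of the list (camera adjusted p = 0.27), with MpExpansin15 at 3.28, MpExpansin32 at 3.25, MpEXL3 at −4.31 and MpEXL6 at −2.64. Limma called 5499 genes (42.1%) over the time course, 3298 with a rise and 2201 with a fall as their largest change. By time, 547 genes were higher and 75 lower at 30 min, 1291 and 315 at 60 min, 1315 and 1134 at 180 min, 1726 and 1447 at 12 h, and 2088 and 1775 at 24 h. With TMM factors 395 genes in place of 622 were called at 30 min, rises were 57.7% of these in place of 87.9%, and they were 53.3% at 60 min in place of 80.4%, 48.2% at 180 min in place of 53.7%, 48.7% at 12 h in place of 54.4%, 51.7% at 24 h in place of 54.1%, and 53% over the time course in place of 60%. Without replicate 3 of darkness 1940 genes in place of 1606 were called at 60 min.

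Far-red light changed fewer genes, with, among genes with a symbol, 3 factor genes as the largest rises at 30 min and 1 methyltransferase and 2 cytochrome P450 genes at 24 h. After 30 min, MpERF2 (Mp7g13760) was at 38.8 ± 4.31 TPM against 11.1 ± 0.317 in darkness (log2 1.72, SE 0.17, n = 3), MpBHLH21 (Mp3g11900) at 95.6 ± 9.83 against 31.5 ± 0.539 (1.57, SE 0.07), and MpR2R3-MYB5 had risen by 1.37; MpLEA-like35 (Mp6g02980) fell by 1.01, a call that ended without replicate 1 or 2 of darkness or 2 or 3 of far-red light (−0.96 to −0.97). At 180 min MpBHLH21 was at 190.5 ± 5.56 TPM against 37.5 ± 1.59 (2.31), MpKOL1 (Mp3g18320), an ent-kaurene oxidase-like gene, at 133.3 ± 2.39 against 28.1 ± 1.57 (2.21, SE 0.09), and the transporter gene MpABCC7 (Mp4g15590) had risen by 2.06. MpLEA-like45 (Mp6g03120, −1.21), MpCupin4 (Mp1g21950, −1.11) and the histone gene MpH2A (Mp3g02370, −1.04) were lower; the calls of MpCupin4 and MpH2A ended without replicate 3 of every group, that of MpH2A also without replicate 3 of far-red light alone (−0.99). At 24 h the methyltransferase gene MpOMT13 (Mp2g21090) was at 120.4 ± 14.2 TPM against 0.134 ± 0.203 (log2 6.75, SE 0.18), MpCYP821A1 (Mp6g18420) at 96.3 ± 10.95 against 0.391 ± 0.326 (6.15), and MpCYP716AA1 (Mp1g01000) at 150.9 ± 9.69 against 3.13 ± 0.97 (5.22). MpLEAL7 (Mp2g26410, −4.04), MpLEA-like48 (Mp6g07560, −3.56) and MpSUT4 (Mp7g14140, −3.48) were lower.

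At 60 min of far-red light, 4 of 7 circadian clock genes rose and 0 fell (camera adjusted p = 3.5e-06; adjusted p = 0.093 with an estimated correlation), among them MpPRR by 1.85 and MpGARP7 by 1.62. In the same samples 3 of 36 bHLH factors rose and 0 fell (camera adjusted p = 5e-06; adjusted p = 0.36 with an estimated correlation), among them MpBHLH21 by 2.46 and MpBHLH4 by 1.87. Without replicate 3 of darkness at 60 min, 4 clock genes (camera adjusted p = 2.8e-05) and 8 bHLH factors (camera adjusted p = 8.7e-06) rose. The 66 phenylpropanoid and flavonoid genes had 1 rise, MpPKS/CHS-like1 by 1.01, and no call of the list (camera adjusted p = 0.87). Their median of 0.15 became −0.02 with TMM factors, and the direction of the test was downward. At 24 h, 18 of 40 histone and replication licensing genes rose and 0 fell (camera adjusted p = 2.9e-08; adjusted p = 0.067 with an estimated correlation). MpH3.1d stood at 3.52 and MpH3.1a at 3.44. In darkness MpH3.1d had itself fallen from time zero by 24 h, so part of its difference is a fall of the reference. Of 19 cell cycle regulators, 8 rose and 0 fell (camera adjusted p = 0.0026; adjusted p = 0.36 with an estimated correlation), MpCYCB_1 by 3.28 and MpCDKB by 2.98. Both genes had fallen from time zero in darkness by 24 h. Of 64 LEA and dehydrin genes, 26 fell and 0 rose (camera adjusted p = 1.3e-08; adjusted p = 0.41 with an estimated correlation). Of 9 plastid isoprenoid genes, 2 rose and 0 fell (camera adjusted p = 0.00032; adjusted p = 0.065 with an estimated correlation), MpDXS2, the entry enzyme of that pathway, by 3.84 and MpDXR2 by 1.89. Of 29 nitrate, peptide and ammonium transporters, 9 rose and 0 fell (camera adjusted p = 0.04; adjusted p = 0.41 with an estimated correlation). MpNPF31 stood at 1.88 and MpNPF22 at 1.87. Of 17 cuticle and surface wax genes, 3 rose and 0 fell (camera adjusted p = 0.017; adjusted p = 0.43 with an estimated correlation), among them MpCYP86H1 by 2.64 and MpCER3a by 1.80. Of the 5 chlorophyll and haem synthesis genes 0 were called by limma, 4 with an adjusted p under 0.05 (4 unadjusted) and below the fold threshold (camera adjusted p = 0.55). MpGUN5 was at 182.7 ± 6.85 TPM against 115.1 ± 7.24 (log2 0.66, SE 0.07). Limma called 1462 genes (11.2%) over the time course, 1035 with a rise and 427 with a fall as their largest change. By time, 33 genes were higher and 5 lower at 30 min, 267 and 36 at 60 min, 223 and 33 at 180 min, 289 and 136 at 12 h, and 780 and 389 at 24 h. With TMM factors rises were 66.7% of the calls at 30 min in place of 86.8%, 74.6% at 60 min in place of 88.1% (of 197 genes in place of 303), 77.8% at 180 min in place of 87.1%, 53.9% at 12 h in place of 68%, 50.7% at 24 h in place of 66.7%, and 54.6% over the time course in place of 70.8%. The 38 genes at 30 min became 74 without replicate 1 of far-red light and 86 and 25 without replicate 1 or 2 of every group, and the 303 at 60 min became 481 without replicate 3 of darkness and 197 and 545 without replicate 1 or 3 of every group.

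**Figure D3:**
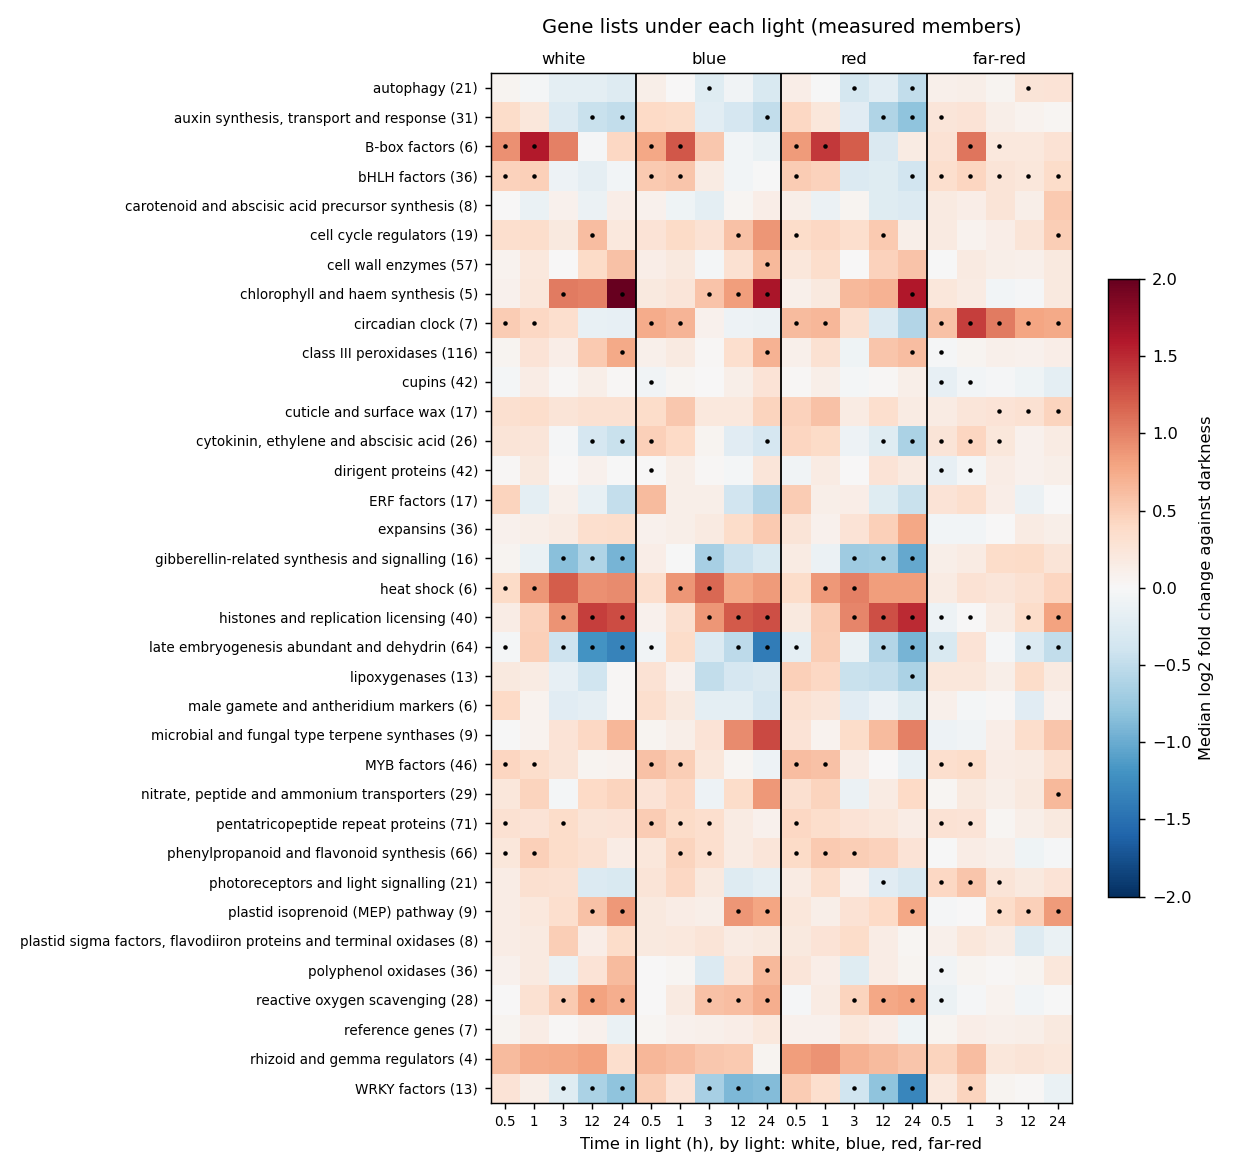
Median log2 fold change against darkness (colour, −2 to 2) of 35 gene lists (lines; measured members in parentheses) at 5 times in h of each of 4 lights; dots mark lists called by camera with the preset correlation. LEA and dehydrin genes had medians of −1.34 in white, −1.4 in blue, −0.93 in red and −0.5 in far-red light at 24 h; under another scaling 133 of the 700 medians changed sign, 94 of them at 30 or 60 min.

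The photoreceptor and light-signalling list was reported gene by gene, with lower transcripts of several receptors in white, blue and red light. MpPHY, the single phytochrome gene, was lower in white light at 12 h (−1.65) and 24 h (−1.23), in blue light at the same times (−1.38 and −1.05), and in red light at 180 min, 12 h and 24 h (−1.33, −1.70 and −1.83). At 30 min it stood above darkness in blue, red and white light (0.9, 0.75 and 0.46), under the fold threshold. It was higher in far-red light at all 5 times (1.09, 1.64, 1.36, 1.17 and 1.12), the last 0.97 with TMM factors and then not called. In darkness MpPHY itself rose above time zero at 12 and 24 h. Its lower values in light at those times are therefore against a raised reference. The cryptochrome gene MpCRY was lower from 60 min to 24 h in white (−1.35, −1.55, −1.85 and −1.77), blue (−1.09, −1.66, −1.58 and −1.35) and red light (−1.62, −1.85, −2.03 and −2.48), with no call in far-red light. MpFHY1, which carries phytochrome to the nucleus in other plants, was lower in white light from 60 min (−1.10, −2.03, −2.38 and −2.18), and in blue (−1.99, −2.21 and −1.67) and red light (−2.14, −2.73 and −2.72) from 180 min. MpNPH3 was lower from 180 min in white (−1.41, −1.47 and −1.2), blue (−1.24, −1.38 and −1.19) and red light (−1.44, −1.58 and −1.95). The phototropin gene MpPHOT was lower from 180 min of red light (−1.08, −1.41 and −1.27) and at 12 h of white light (−1.12), and MpNCH1 at the same points (−1.02, −1.55 and −1.26, and −1.16). The LOV-domain gene MpLOVA was higher at every time in white (2.24, 3.25, 1.67, 2.18 and 2.08), blue (2.38, 3.14, 1.57, 2.11 and 1.57) and red light (2.21, 2.95, 1.76, 2.18 and 2.06), and in far-red light at 60 min (1.75) and 24 h (1.51). MpRUP, a repressor of ultraviolet-B signalling in other plants, was higher in blue light at every time (1.13, 3.33, 3.1, 1.61 and 1.37), from 60 min in white (2.93, 1.91, 1.03 and 1.32) and far-red light (1.00, 1.15, 1.41 and 1.15), and in red light at 180 min (1.21) and 24 h (1.07); with quantile normalization its calls at 24 h of red and of far-red light ended.

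MpCOP1, a ubiquitin ligase of light signalling, was higher at 60 min of white (1.68), blue (1.88) and far-red light (1.02) and lower at 12 and 24 h of red light (−1.16 and −1.04, the latter not called without replicate 3). MpDET1 was higher at 60 min of white (1.89), blue (2.01) and red light (1.08), and at 180 min of blue (1.79) and far-red light (1.11). MpCRY-DASH was higher at 180 min of white (1.10) and blue light (1.97), MpSPA1 at 60 min of blue light (1.06), and MpFKF was lower at 24 h of blue (−1.05) and red light (−1.19). MpBHLH6, also named MpPIF, was called in red against far-red light alone (−1.30 at 12 h and −1.24 at 24 h). MpCOP10, MpDDB1, MpEID1, MpHY1, MpHY2, MpTZP1 and MpUVR8 had 0 calls by limma in the 35 contrasts. In far-red light the list had 4 rises and 0 falls of 21 at 60 min (camera adjusted p = 3e-05; adjusted p = 0.41 with an estimated correlation), and 5 rises without replicate 3 of darkness (camera adjusted p = 4e-05). Of 140 calls of these genes in the 35 contrasts, 14 ended when 1 library was left out. Without replicate 3 of darkness at 60 min MpCRY in blue light came to −0.92 and MpFHY1 in white light to −0.98. Without replicate 2 of that group MpSPA1 in blue light came to 0.96, MpDET1 in red light to 0.99 and, in far-red light, MpCOP1 to 0.96 and MpRUP to 0.93. The far-red call of MpRUP also ended without replicate 1 of darkness (0.95) or 2 of far-red light (0.96), and that of MpCOP1 without replicate 1 of far-red light (0.99). MpPHY lost its call at 30 min of far-red light without replicate 2 of that light (0.99) and at 24 h of blue light without replicate 1 of darkness (−0.99). MpRUP at 12 h of white light ended without its replicate 3 (0.98) and MpNCH1 at 180 min of red light without its replicate 1 (−0.99). MpCOP1 at 24 h of red light ended without replicate 1 of darkness (−0.98) or 3 of red light (−0.96), and MpFHY1 in blue against red light at 24 h without replicate 3 of red light (0.99).

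Blue against red light is the pair named in the title of the series, which speaks of antagonism between their signalling. At 24 h, 289 genes were higher and 139 lower in blue light, among the former the dioxygenase gene MpDOXC30 (Mp6g01140) at 28.3 ± 1.59 TPM against 2.37 ± 0.0546 (log2 3.12, SE 0.12, n = 3), MpERF10 at 43.1 ± 5.26 against 4.25 ± 0.0998 (3.06), MpKOL1 at 95.4 ± 6.70 against 10.7 ± 0.480 (3.04), MpCYP821A1 (3.02) and the dirigent protein gene MpDIR5 (Mp8g07540) at 201.5 ± 20.1 against 29.4 ± 7.11 (2.75). MpLEA-like18 (Mp4g05730, −2.56), MpLEAL1 (Mp4g09300, −2.52), MpLEA-like19 (Mp4g05750, −2.48), MpLEA-like49 (Mp6g11340, −2.32) and MpSUT4 (−2.13) were lower in blue light. At 180 min, MpPPR_16 (Mp1g13160, 2.06), MpCRY-DASH (Mp1g25600) at 41.7 ± 1.2 TPM against 9.92 ± 1.43 (1.97), the wax gene MpCER1 (Mp3g17080, 1.93), MpRUP (Mp2g18040) at 81.7 ± 2.42 against 21.3 ± 1.82 (1.89) and MpPKS/CHS2 (1.83) were higher in blue light. MpBBX6 (Mp2g16350, −1.91), MpGH31.8 (−1.50), MpCYP707A (Mp2g25940, −1.44), MpPKS/CHS15 (Mp4g14200, −1.28) and MpUGT32 (Mp7g18730, −1.27) were lower. At 30 min the bHLH factor gene MpBHLH4 (Mp2g00930) was at 1.80 ± 0.316 TPM in blue against 8.95 ± 2.06 in red light (log2 −1.81, SE 0.31), and MpPAL7 (Mp4g14110, −1.12) and MpPR6b (Mp8g12150, −1.09) were lower. The call of MpPAL7 ended without replicate 3 of blue (−1.04, adjusted p = 0.064) or 2 of red light (−0.76), and that of MpPR6b without replicate 2 of blue (−0.88) or 1 or 2 of red light (−0.76 and −0.86).

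By list, 4 of 16 gibberellin-related genes were higher in blue than in red light at 24 h and 0 lower (camera adjusted p = 4.3e-07; adjusted p = 0.044 with an estimated correlation). MpKAOL2 stood at 2.48. Of 13 lipoxygenases, 3 were higher and 0 lower (camera adjusted p = 0.00018; adjusted p = 0.21 with an estimated correlation), among them MpLOX4 at 1.75 and MpLOX10 at 1.75. Of 36 bHLH factors, 5 were higher and 0 lower (camera adjusted p = 6.3e-05; adjusted p = 0.43 with an estimated correlation), among them MpBHLH21 at 2.53 and MpBHLH40 at 2.10. Of 64 LEA and dehydrin genes, 20 were lower in blue light and 0 higher (camera adjusted p = 0.00083; adjusted p = 0.62 with an estimated correlation). The 28 reactive oxygen scavenging genes moved down as a list (camera adjusted p = 0.00015; adjusted p = 0.079 with an estimated correlation), with a median of −0.25; 0 members were called by limma, 20 with an adjusted p under 0.05 (22 unadjusted) and below the fold threshold. At 60 min the photoreceptor list was higher (2 of 21 higher, 0 lower; camera adjusted p = 2.5e-12; adjusted p = 0.093 with an estimated correlation). MpRUP stood at 2.68 and MpCOP1 at 1.39. MpCOP1 at 180 min (1.12), MpDET1 at 180 min (1.44), and MpCRY (1.13), MpFHY1 (1.05) and MpPHOT (1.09) at 24 h were also higher in blue light. At 30 min the phenylpropanoid and flavonoid list was lower (1 of 66 lower, 0 higher; camera adjusted p = 1.8e-07; adjusted p = 0.079 with an estimated correlation). In the test of all 5 times limma called 603 genes (4.6%), with the largest difference upward in blue light for 403 and downward for 200. By time, 0 genes were higher and 6 lower at 30 min, 16 and 4 at 60 min, 102 and 33 at 180 min, 86 and 47 at 12 h, and 289 and 139 at 24 h. The 6 genes at 30 min became 3 and 15 without replicate 2 or 3 of red light, 3 and 13 without replicate 2 or 3 of every group, and 0 with a filter at 10 TPM. Intensity differed too, at 30 to 40 µmol m⁻² s⁻¹ for blue and 80 to 90 for red light, so wavelength and intensity cannot be separated here.

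Against darkness, blue and red light moved many genes in the same direction and few apart. At the 5 times 498, 1248, 1892, 2337 and 2708 genes were called in both lights in the same direction, and 0, 0, 0, 1 and 4 in opposite directions; at 30 min independent lists would share 24.6 rises. In all, 4354 genes were called in the same direction at 1 or more times and 5 in opposite directions. At 12 h Mp7g05890 was at 563 ± 57.2 TPM in blue, 53.6 ± 3.82 in red and 228 ± 11.4 in darkness (difference 3.37, SE 0.06). At 24 h Mp7g05530 was at 395 ± 34.7 TPM in blue, 6.37 ± 0.355 in red and 56.3 ± 0.623 in darkness (5.74, SE 0.08), and Mp7g06740 at 71.1 ± 8.46, 5.50 ± 0.734 and 15.4 ± 5.08 (3.47, SE 0.13). These 3 have no symbol and were chosen after their values were seen. The others were MpKOL1, at 95.4 ± 6.70, 10.7 ± 0.480 and 30.4 ± 3.04 TPM, and MpBHLH21, at 104.9 ± 7.07 in blue, 17.3 ± 1.24 in red and 39.6 ± 3.64 in darkness. The blue minus red difference of these 5 genes had a limma adjusted p of at most 2e-33. A large difference follows from their choice by opposite calls, so this p is no separate evidence. Across genes, the fold changes of both lights correlated with r of 0.933, 0.963, 0.941, 0.961 and 0.926. Both share the dark libraries, which in 20 simulations of unchanged groups gave r of about 0.499 and a covariance of 0.0074 at 30 min against 0.1912 in the data, with 0 genes called in common in either direction. The simulated r and the 0 calls follow from the setup, with noise drawn from the spread within groups. A shift of the whole dark group, as from its plates, was not simulated, so the simulations cannot exclude one. With separate references (1 light against time zero) the 5 opposite genes became 10 or 16, with pseudocounts of 0.1 and 5 they became 11 and 3, and with the adjusted p alone 346.

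**Figure D4:**
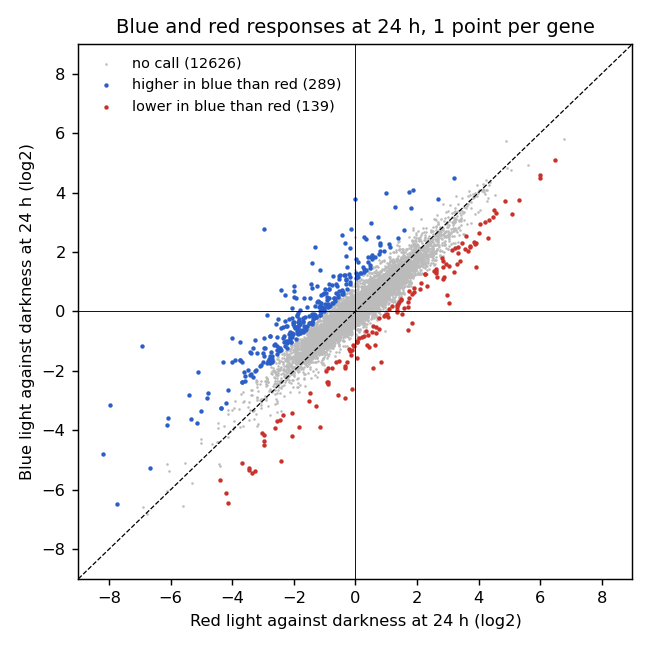
Log2 fold change against darkness at 24 h in blue light (vertical) and red light (horizontal), 1 point per gene; the dashed line marks equal change, with colours for 289 genes called higher and 139 called lower in blue than in red light by limma and grey for the others. Most points lie along the line, with 2708 genes called in both lights in the same direction and 4 in opposite directions.

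Red against far-red light sets apart the pair of lights that phytochrome absorbs in its inactive and active forms. Red light was also given at a higher intensity than far-red light, so wavelength and intensity cannot be separated in this comparison. At 24 h the aldolase gene MpFBA4 (Mp2g02260) was at 245.8 ± 4.26 TPM in red against 20.4 ± 1.03 in far-red light (log2 3.53, SE 0.06, n = 3), the ferric reductase gene MpFRO2 (Mp3g20260) was higher by 3.28 and the terpene synthase gene MpMTPSL2 (Mp3g18500) by 3.27. MpMLS5 was at 0.314 ± 0.0996 TPM in red against 149.1 ± 17.4 in far-red light (−6.83, SE 0.13), and MpCYP821A1 (−6.58) and MpOMT13 (−6.29) were lower. At 30 min MpPKS/CHS14 was at 74.5 ± 4.35 TPM against 8.55 ± 1.35 (2.99), and MpPKS/CHS13 (Mp4g14180, 2.81) and MpPKS/CHS21 (2.72) were higher; the dioxygenase gene MpDOXC3 (Mp1g12420, −1.55), MpEXL6 (−1.49) and MpBHLH21 (−1.42) were lower. Of 66 phenylpropanoid and flavonoid genes, 17 were higher in red light at 30 min and 0 lower (camera adjusted p = 1.3e-06; adjusted p = 0.093 with an estimated correlation). Of 40 histone and replication licensing genes, 19 were higher at 180 min and 0 lower (camera adjusted p = 8.1e-07; adjusted p = 0.093 with an estimated correlation). MpMCM6 stood at 2.33 and MpMCM3 at 2.16.

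At 24 h, 13 of 28 reactive oxygen scavenging genes were higher in red than in far-red light and 0 lower (camera adjusted p = 1.7e-06; adjusted p = 0.036 with an estimated correlation). MpMDHAR3 stood at 2.67 and MpGPX2 at 2.58. Of 116 class III peroxidases, 39 were higher and 7 lower (camera adjusted p = 0.00083; adjusted p = 0.53 with an estimated correlation). MpPOD109 stood at 3.14, MpPOD82 at 3.11, MpPOD26 at −5.20 and MpPOD169 at −2.46. Of 5 chlorophyll and haem synthesis genes, 3 were higher and 0 lower (camera adjusted p = 0.013; adjusted p = 0.3 with an estimated correlation), among them MpCHLI1/2-like at 1.53 and MpGUN5 at 1.38. Of 16 gibberellin-related genes, 11 were lower and 1 higher (camera adjusted p = 0.00015; adjusted p = 0.093 with an estimated correlation). MpKAOL2 stood at −4.65, MpKAOL1 at −3.94 and MpKOL3 at 1.88. Of 26 cytokinin, ethylene and abscisic acid genes, 11 were lower and 0 higher (camera adjusted p = 9.1e-05; adjusted p = 0.37 with an estimated correlation). The cytokinin synthesis genes MpIPT2 and MpLOG stood at −4.71 and −4.36. Of 21 autophagy genes, 10 were lower and 0 higher (camera adjusted p = 0.00024; adjusted p = 0.4 with an estimated correlation), among them MpATG18c at −1.49 and MpATG8a at −1.47. Of 7 clock genes, 5 were lower and 0 higher (camera adjusted p = 0.0058; adjusted p = 0.42 with an estimated correlation), among them MpGARP7 at −3.0 and Mp1R-MYB11 at −1.72. Of 21 photoreceptor and light-signalling genes, 9 were lower and 0 higher (camera adjusted p = 0.012; adjusted p = 0.6 with an estimated correlation). MpCRY stood at −3.03 and MpPHY at −2.96. In the test of all 5 times limma called 4343 genes (33.3%), with the largest difference upward in red light for 2143 and downward for 2200. By time, 154 genes were higher and 54 lower at 30 min, 427 and 306 at 60 min, 942 and 1162 at 180 min, 1225 and 1261 at 12 h, and 1303 and 1646 at 24 h. With TMM factors the share of higher genes was 57.6% at 30 min in place of 74%, 47% at 60 min in place of 58.3%, 47.7% at 180 min in place of 44.8%, 51.3% at 12 h in place of 49.3%, 53.2% at 24 h in place of 44.2%, and 53.5% over the time course in place of 49.3%; the median of all genes was 0.12 at 30 min and −0.103 at 24 h, and −0.012 and 0 with those factors.

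Continued darkness, the reference of all light comparisons, had 3 polyphenol oxidase genes as its largest falls of genes with a symbol at 24 h. MpPPO71 was at 5.32 ± 1.07 TPM at 24 h against 58.2 ± 3.95 at time zero (log2 −3.24, SE 0.10, n = 3), and the oxidase genes MpPPO45 (Mp5g21450, −2.77) and MpPPO17 (Mp5g15320, −2.75) were lower. The lipid transfer protein gene MpLTP-like65 (Mp3g06560) was at 168.6 ± 27.6 TPM against 18.5 ± 3.06 (3.12, SE 0.14), and MpPR1o (Mp5g16820, 2.49, SE 0.39) and MpGH19.8 (Mp4g20470, 2.43) were higher. At 180 min MpERF2 (1.15) and the receptor kinase gene MpRLK-Pelle_SD-2b6 (Mp7g16250, 1.02) were higher and the histone gene MpH3.1d (Mp7g16200, −1.01) lower; the call of the kinase gene ended without replicate 1 or 3 of time zero or 2 or 3 of 180 min (0.96 to 0.99), and that of MpH3.1d without replicate 3 of either (−0.94 and −0.95). Of 36 polyphenol oxidases, 7 fell, 2 rose and 27 were not called at 24 h (camera adjusted p = 2e-04; adjusted p = 0.34 with an estimated correlation), the rises being MpPPO4 by 2.34 and MpPPO52 by 1.48. Of 40 histone and replication licensing genes, 7 fell and 1 rose (camera adjusted p = 0.00085; adjusted p = 0.3 with an estimated correlation). MpH2A stood at −2.13, MpH3.1d at −1.77 and MpH2A.X.2 at 1.08. Of 19 cell cycle regulators, 5 fell, among them MpCYCB_1 (−2.18) and MpCDKB (−1.57), and 0 rose, without a call of the list (camera adjusted p = 0.43). Their median of 0.05 and mean of −0.26 differed in sign, and the median became −0.07 with TMM factors. Of 26 cytokinin, ethylene and abscisic acid genes, 2 rose and 0 fell (camera adjusted p = 0.00018; adjusted p = 0.41 with an estimated correlation), the cytokinin receptor gene MpCHK2 by 1.74 and MpCKX1 by 1.11. At 12 h, 5 of 116 class III peroxidases fell and 0 rose (camera adjusted p = 1e-06; adjusted p = 0.36 with an estimated correlation), among them MpPOD82 at −1.27 and MpPOD158 at −1.24. MpPHY was higher than at time zero at 12 h (1.26) and 24 h (1.29), the 1 rise of the 21 photoreceptor genes at 24 h (camera adjusted p = 0.017; adjusted p = 0.62 with an estimated correlation).

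Over the time course in darkness limma called 518 genes (4%), 218 with a rise and 300 with a fall as their largest change. By time, 0 genes were higher and 0 lower at 30 min (704 had an unadjusted p under 0.05 in limma), 10 and 18 at 60 min, 15 and 12 at 180 min, 118 and 146 at 12 h, and 159 and 250 at 24 h. With TMM factors rises were 25% of the calls at 180 min in place of 55.6%, 21.6% at 12 h in place of 44.7%, 24.5% at 24 h in place of 38.9%, and 25.8% over the time course in place of 42.1%; the median of all genes was 0.11 at 12 h and 0.1 at 24 h, and −0.035 and −0.013 with those factors. Without replicate 1 or 3 of every group the 28 genes at 60 min became 18 and 44, and without replicate 3 the 27 genes at 180 min became 46; a single library left out gave 22 to 39 and 22 to 34.

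Responses changed with time in all 4 lights. The response at 24 h differed from that at 30 min for 3228 genes in white light (1483 more positive, 1745 more negative), 3564 in blue (1427 and 2137), 4073 in red (1559 and 2514) and 1056 in far-red light (648 and 408). The excess of more negative genes turned with TMM factors, to 1764 more positive and 1385 more negative in white, 1890 and 1419 in blue, and 2133 and 1789 in red light, with 604 and 435 in far-red light. Of 382, 668, 622 and 38 genes called at 30 min, 134, 119, 188 and 18 were called at 24 h with the same sign and 13, 17, 28 and 0 with the opposite sign. MpERF2 went from a rise of 2.04 at 30 min to −1.10 at 24 h of blue light, and MpCYP707A, an abscisic acid hydroxylase gene, from 1.99 to −2.04 in white light. In all, 6383 genes were called in at least 1 light and 1076 in all 4; 238 were called in white light alone, 262 in blue, 557 in red and 146 in far-red light, which does not test whether lights differ. Tested directly at the 5 times, white differed from blue light in 23, 8, 77, 135 and 249 genes and from red light in 4, 28, 84, 66 and 117. White differed from far-red light in 171, 762, 2072, 2336 and 2272 genes, and blue from far-red light in 181, 624, 1904, 1915 and 1855.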

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

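Of the tests below, those of TMM scaling and of separate references were chosen only after the result was seen. Each result here was picked out because the response to light differed between lights or between times, by limma's test of the difference itself (adjusted p of at most 1e-11 for the single genes); among 94 named genes, 11 changed in opposite directions.

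The responses at 24 h and at 30 min differed for 3228 genes in white, 3564 in blue, 4073 in red and 1056 in far-red light. The phytochrome gene MpPHY was lower than darkness from 12 h in white and blue light and from 180 min in red light, and higher in far-red light. In darkness it had itself risen above time zero at 12 and 24 h. At 30 min MpPHY stood above darkness in white, blue and red light, under the fold threshold. Its difference from far-red light was −2.69 (log2) for red light at 180 min. At 12 h it was −2.82 for white, −2.55 for blue and −2.88 for red light, and at 24 h −2.36, −2.18 and −2.96. MpMLS5 at 12 h was lower in white (−6.25), blue (−6.09) and red light (−6.67) than in far-red light. MpKOL1 was lower than in far-red light at 180 min in white (−3.35) and red light (−3.32), at 12 h in the same lights (−3.44 and −3.48), and at 24 h in white (−3.36) and red light (−3.75). At 24 h it was lower in white than in blue light (−2.64) and higher in blue than in red light (3.04). MpBHLH21 was lower in red than in far-red light at 12 h (−3.37) and 24 h (−3.95), and higher in blue than in red light at 24 h (2.53).

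MpCYP707A at 24 h was lower in white (−3.32), blue (−2.83) and red light (−3.49) than in far-red light. MpDOXC30 was lower than in far-red light at 12 h in white (−3.78) and red light (−4.04), and at 24 h in white (−4.45) and red light (−5.31). MpDIR5 at 24 h differed from far-red light by −4.68 in white and −4.63 in red light. MpLEAL7 at 180 min was lower in white than in far-red light (−2.50). MpLEAL1 at 12 h was lower in white than in blue (−3.43) and in far-red light (−3.29). Over time, the response at 24 h minus that at 30 min was −3.14 in blue and −2.97 in red light for MpERF2. It was −4.03 in white, −3.63 in blue and −3.64 in red light for MpCYP707A, and −2.99 in white light for MpLEA-like18.

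The early responses were mostly rises. A few abundant transcripts of the dark libraries might hold down all other TPM values. Then the median at 30 min of blue light (0.169) should drop below its midpoint to 0 without the 50 genes of highest mean TPM. It was 0.113, which argues against those 50 genes as the whole cause. They were ranked over all 78 libraries. Transcripts abundant mainly in darkness may remain, so the test cannot exclude these. If scaling between libraries set the direction, rises should be no more than 50% of the calls at 30 min of blue light with TMM factors. They were 60.5% in place of 88%, which argues against it as the whole cause for that contrast, though the size of the excess depends on the scaling. At 60 min the share with those factors was nearer 50%, at 54.7% in blue and 53.3% in red light. The median of all genes at 30 min of blue light turned from 0.169 to −0.07, so the direction of the general shift depends on the scaling. A general rise of messenger RNA per cell cannot be seen in TPM and stays open, untested.

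Blue and red light changed the same genes in the same direction, 4354 of them. Both were compared with the same dark libraries, which alone should give few such genes once each light has its own reference. With time zero as the reference of 1 light, 3675 or 3709 genes were called in the same direction, which argues against the shared libraries as the cause. What stays open, untested, is whether both lights act through separate receptors or through photosynthesis and growth; the plates also differed from those kept in darkness.

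Other splits of the same libraries were counted for each result, with 100 splits each. The real split alone gave the value (1 of 100 splits), so a chance division of the libraries is unlikely to give it, for the genes changed by white (4878, highest other split 4506), blue (4947 and 4091), red (5499 and 4841) and far-red light (1462 and 1256). The same holds for blue against red (603 and 560), red against far-red light (4343 and 2934), continued darkness (518 and 375), the 5 genes with opposite changes (highest other 0), calls at single times (44496 and 17732, median split 5661) and gene lists (312 and 218). The median split still gave 157 list calls, so the total does not support any single list call. Plate follows the treatment, so no split can tell light from plate. Some splits keep a real division of 2 groups at some time, 44 of the 100 for white light; the highest split without one gave 1 gene for white, 0 for blue, 0 for red and 10 for far-red light, 0 for blue against red and 2 for red against far-red light. In continued darkness 0 splits keep one and the highest still gave 375 genes (median 30). For time dependence, splits as large numbered 11 for white light (3228, highest other 3854) and 1 for blue light (3564 and 3407). They numbered 4 for red (4073 and 4188) and 3 for far-red light (1056 and 1177). A real division was kept by 25, 16, 15 and 14 splits for white, blue, red and far-red light. The highest of the other splits gave 0, 1, 1 and 1 genes. No split without a real division was as large, so these counts depend on how many splits keep one. They therefore cannot decide whether the response to any light changed with time. At single times 3 against 3 libraries allow 10 splits, too few for a share under 0.05. The real split gave the highest count (1 of 10 splits) in 34 of 35 contrasts, with up to 3863 genes in red light against at most 133 in any other split; in darkness at 30 min all 10 splits gave 0 genes.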

How the results depend on the processing

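Of the settings here, leaving out the 60 min libraries, leaving out single libraries and median centring were tests chosen only after the data were seen. No time-course, time-dependence, opposite-direction or list count, nor the total of calls at single times, moved by more than 1.5 times with either filter, TMM factors, quantile normalization, the robust fit or only the groups of the comparison. With median centring or without the 60 min libraries, of these results only the time-course counts and the total were computed. None of them moved by more than 1.5 times. None of 198 single-gene values reversed under 14 alternatives (2764 comparisons). Only values called in the main fit could count as reversed. The filters, the robust fit, only the groups of the comparison, the block and both changed thresholds leave fold changes as they are by construction. The count therefore tests only the pseudocounts, the scalings and the replicates left out. A count-based alternative was not run, since the values are not counts. The fold threshold, the pseudocount and the reference moved counts. With the adjusted p alone, white, blue, red and far-red light gave 12362, 12416, 12505 and 11006 genes, blue against red 7419, red against far-red 12191, darkness 9724, opposite directions 346, calls at single times 248466, and time dependence 9231, 9483, 9815 and 6364. With a fold threshold of 2 (log2) the same counts were 1192, 1113, 1303, 247, 77, 890, 43, 1, 8396, and 778, 695, 882 and 185. Both follow from the threshold itself. With a pseudocount of 0.1 far-red light gave 2236 genes, blue against red 948, darkness 1065 and opposite directions 11; with 5 they gave 789, 330, 238 and 3, calls at single times 29324 and time dependence in far-red light 553. Of 35 counts at single times, 15 rose by more than 1.5 times with 0.1 and 23 fell by more than that with 5. With only the groups of the comparison, darkness at 60 min against time zero gave 14 genes in place of 28. Genes near 0 TPM gain or lose fold change with the pseudocount by construction. With time zero as the reference far-red light gave 2312 genes, and with separate references blue against time zero gave 10 and red against time zero 16 opposite genes; the cause was not tested. Of list tests, 2 passed with an estimated correlation and 903 with fry, which asks another question.

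Replicates left out in turn gave 4927 to 5081 genes for white, 4940 to 5172 for blue, 5552 to 5827 for red and 1424 to 1702 for far-red light, 622 to 643 for blue against red, 4348 to 4468 for red against far-red, 529 to 575 for darkness, 6 to 7 with opposite directions and 285 to 306 list calls. Without replicate 3 of darkness at 60 min alone, the 7 time courses gave 5018, 5098, 5715, 1605, 607, 4344 and 524 genes, with 5 opposite and 315 list calls. Of 210 counts with 1 of the 78 libraries left out, 4 moved by more than 1.5 times, and 6 of 114 gene values lost their call. Without the 60 min libraries the 7 time courses gave 4636, 4695, 5153, 1330, 594, 4220 and 496 genes. Replicate numbers did not pair libraries across groups (mean r of residuals −0.002 for the same number and 0.001 for others, over 325 group pairs); with the number as a block, white light gave 4878 genes, far-red light 1462 and blue against red 604. With TMM factors the calls of MpPHY in far-red light at 24 h and of MpRLK-Pelle_SD-2b6 in darkness at 180 min ended, as did those of MpRUP at 24 h of red and far-red light with quantile normalization and of MpPAL7 and MpPR6b at 30 min with only the groups of the comparison. With a pseudocount of 5, 17 of the 198 values lost their call. The depth of the libraries is unknown, so no limit from depth can be given for genes near 0 TPM.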

Other observations

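Of the tests below, those on the genes that also rose in far-red light were chosen only after the result was seen. Several lists not described so far moved in parts. At 60 min of white light the sigma factor gene MpSIG5 was at 111.9 ± 8.97 TPM against 5.97 ± 0.817 in darkness (log2 4.02, n = 3) and MpSIG2 fell by 1.5, while the list of 8 plastid sigma factors, flavodiiron proteins and terminal oxidases was not called (1 rose, 1 fell, 6 not called; camera adjusted p = 0.86), with a median of 0.18 that became −0.03 with TMM factors. Of 6 heat shock genes, 2 rose and 0 fell (camera adjusted p = 0.013; adjusted p = 0.4 with an estimated correlation), MpHSP90-1 by 1.33 and MpHSP90-2 by 1.19; without replicate 3 of darkness 3 rose (camera adjusted p = 0.01). Of 4 rhizoid and gemma regulators, 2 rose and 0 fell (camera adjusted p = 0.22), MpGCAM1 by 2.89 and MpKAR by 1.08. Of 17 ERF factors, 4 rose and 4 fell (camera adjusted p = 0.47), with MpERF15 at 2.02, MpERF2 at 1.64, MpERF10 at −2.64 and MpERF11 at −1.53. Of 6 male gamete and antheridium markers, limma called 0 at 24 h of white, blue, red or far-red light; 0, 4, 3 and 3 had an adjusted p under 0.05 (as many unadjusted), below the fold threshold (camera adjusted p = 0.94, 0.75, 0.89 and 0.97).

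At 24 h of red light, 14 of 42 dirigent protein genes rose and 7 fell (camera adjusted p = 0.62), with MpDIR27 at 3.50, MpDIR2 at 3.46, MpDIR39 at −6.06 and MpDIR5 at −2.87. Of 9 terpene synthases of microbial and fungal type, 5 rose and 2 fell (camera adjusted p = 0.23), with MpMTPSL-like at 3.32, MpMTPSL2 at 3.21, MpMTPSL5 at −1.22 and MpMTPSL1 at −1.11. Of 7 reference genes, 1 rose (MpAPT by 1.36) and 0 fell in red light (camera adjusted p = 0.96), with a median of −0.09 and a mean of 0.13; MpAPT also rose by 1.04 in blue light. At 24 h of far-red light, 3 of 42 cupins rose and 8 fell (camera adjusted p = 0.073); MpPR15a was at 11.7 ± 3.91 TPM and listed at 0 in all 3 dark libraries, MpCupin43 stood at 1.05, MpCupin57 at −1.46 and MpCupin84 at −1.41. Of 8 carotenoid and abscisic acid precursor genes, 1 was higher and 3 lower in red than in far-red light at 24 h (camera adjusted p = 0.52), with MpABA1 at 1.29, MpABA4 at −3.58 and MpNCED at −2.39. The count adjusted over the list alone differed from that over all genes in 2 tests: 1 in place of 0 polyphenol oxidases in blue against red light at 30 min, and 3 in place of 2 cupins in far-red light at 180 min.

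Several named genes higher in blue than in red light at 24 h, such as MpKOL1, MpCYP821A1 and MpBHLH21, had also risen in far-red light, unlike Mp7g05530 (−1.75), Mp7g06740 (0.25, not called) and at 12 h Mp7g05890 (−0.21, not called), and from the former a hypothesis was written: blue light may leave on a far-red type response that red light ends. Of the 289 genes higher in blue than in red light, 66 were higher in far-red light than in darkness against 17.3 expected of independent lists, a ratio of 3.82. The hypothesis predicts an excess, but these 289 include the genes it was written from. The overlap is therefore not an independent test of it. Of the 139 lower genes 35 were lower in far-red light against 4.1 expected (ratio 8.45), though opposite calls were also in excess (18 of the 289 lower against 8.6, ratio 2.09), and across all genes blue minus red correlated with far-red minus darkness at r = 0.097. With an excess in both directions, the ratio alone does not single out the hypothesis. A response to blue light that is weaker than that to red light in every gene is the rival. Of the 289 genes 17.6%, and of the 66 genes 43.9%, rose in blue and not in red light. With no dark library shared between choice and score, the latter share was 45.5% of 66 or 27.9% (95% interval 18.8 to 38.6) of 86 genes. That interval counts genes as independent, which they are not, so it does not measure the spread over libraries. The lower share lies too near the 25% set as the bound for these shares to exclude the rival. The rival forbids a gene that is higher in blue light than in both red light and darkness, or lower than in both. Of the 289 genes, 62 were called higher in blue light than in darkness. Of the 139 lower genes, 53 were called lower in blue light than in darkness. These values argue against the rival for those genes, which include the 4 called in opposite directions by blue and red light at 24 h. For the other genes it stays open. Intensity (30 to 40 against 80 to 90 µmol m⁻² s⁻¹) and plate follow the light, so they cannot be told apart from wavelength.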
